A study of Escherichia coli str. K-12 substr. MG1655 with 22 samples.

How the data were processed

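Transcript levels of Escherichia coli K-12 MG1655 were measured by RNA sequencing in 22 libraries. Per the labels' protocols, cells grew aerobically in M9 minimal medium to exponential phase on glucose, xylose or acetate at 4 g/L or on glycerol at 0.2% v/v, rRNA was depleted with Ribo-Zero, and stranded libraries were made with a KAPA kit and read from both ends. The groups came from the sample titles: the wild type on each of the 4 carbon sources, lines evolved on a single carbon source and grown on that source, and 4 strains evolved on alternating carbon sources, each grown on both of its sources.

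The deposited tables hold FPKM (fragments per kilobase of gene, scaled to the number of mapped fragments) with lower and upper confidence limits and a status for each of 4497 genes, per the file headers, which have the layout of a Cufflinks gene table. The submitters' processing notes name FastQC, Bowtie2, Cufflinks, Cuffnorm and Cuffdiff. Their versions, order and settings, the annotation, whether counting used the strand, and any scaling between libraries are not given in the sources used here. Coordinates are those of the files, on the MG1655 chromosome of assembly ASM584v2, and are printed 1-based. Gene identities were matched to the RefSeq gene table of the same assembly: 4354 genes matched by coordinates, 129 by symbol only and 14 did not match. For 9 symbols shared by 55 rows (mostly insertion sequence copies) each row was kept apart by its own identifier, and values of such copies are uncertain because reads can be split between them.

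FPKM are not counts, so no count model was used. The depth was estimated from the files: from the widths of the confidence limits, taken as 2 SD of a count on each side, the libraries hold 1461482 (Ac3) to 5696470 (Glc3) fragments with a median of 3749068, and from the smallest values above 0 they hold 1345932 to 4655226 fragments. For genes with a mean of 20 to 50 FPKM over all libraries the deposited limits lie at a median of 15.2% to 44.7% of the value. They are widest in Glc/Ac Glc Specialist on acetate, where FPKM are lowest, and next widest, 34.7%, in Ac3. These limits cover counting error only.

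FPKM were scaled by the median ratio of each library to the geometric mean of all libraries over 3566 genes above 0 in every library, with factors of 0.215 (Glc/Ac Glc Specialist on acetate) to 1.71. Left out were 108 rRNA and tRNA genes, 1 gene whose status was not OK, and 174 genes with a mean below 1 FPKM, which left 4214 genes. Tests ran on log2(scaled FPKM + 1), so differences of low genes are understated. The linear models of limma 3.58.1 (R 4.3.3), with a variance trend and robust empirical Bayes moderation, were fitted to all 22 libraries because most groups hold 1 library. A model of carbon source plus strain class (13 residual degrees of freedom) gave the comparisons between carbon sources, of the evolved lines with the wild type over all sources, and of the alternating strains. A model with a mean for every class on every source (6 residual degrees of freedom) gave the comparisons within a source and the tests of whether a difference depends on the source. There the lone libraries were assumed to vary like the lines of a group. Adjusted p-values are Benjamini-Hochberg values over the 4214 genes, with 0.05 as the threshold. Tables were handled with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

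The 30 gene lists, the tests, the rule for named genes and most of the other processing choices tried were fixed before the data were examined. Each list was tested against the other genes with camera of limma at a preset correlation of 0.01 and again with an estimated correlation, and adjusted over the 30 lists within a comparison. The rule for named genes took the 6 largest rises and the 6 largest falls past the threshold with the same direction in every matched pair of groups, up to 4 members past the threshold of each list that passed or belongs to the carbon source, and always ptsG, pck, aceA, acs, glpK, glpF, xylA, xylF, pyrE, rph, fliC, gadB and ompF. Where nothing passed, the 5 smallest p-values were taken. A scan with no test took genes at 10 or more FPKM in every other library of a carbon source and at least 10 times lower in 1 library, or at least 10 times higher and at 10 or more FPKM, and runs of 3 or more neighbours.

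The models were tested on simulated data with 200 of 4214 genes changed. For acetate versus glucose, 38% of 2-fold, 82% of 4-fold, 84% of 8-fold and 96% of 16-fold changes were recovered. The shares were 34%, 70%, 96% and 92% for evolved lines against wild type over all sources and 2%, 38%, 60% and 76% on glucose. For Glc/Gly Generalist they were 20%, 58%, 84% and 76%. Of 4014 unchanged genes, 9, 13, 3 and 11 were called. These rates may not hold for the real libraries.

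The alternatives were pseudocounts of 0.1 and 10, no filter or a mean of at least 10 FPKM, FPKM as deposited or quantile normalization, rRNA and tRNA genes kept, all genes kept whatever the status, no variance trend or robust moderation, the line number as a block, smaller sets of libraries, and leaving out each library in turn. Alternatives added after seeing the data left out the libraries whose glycerol or xylose genes go against their labels, kept genes of 600 nt or more, added a term for the library set (7 libraries in which genes shorter than 200 nt have FPKM above those of genes of 900 nt or more, and 15 in which they have lower ones), or used 1 library set alone. Also after seeing the data, the genes called for the glucose lines were looked up in the 3 evolved glucose libraries that share the library set of the wild type, nearer to the lines where they lay past halfway from the wild type (log2). Count models were not run, as the values are FPKM. No pair of libraries held identical values.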

Results

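Transcript levels were measured in 22 RNA sequencing libraries of E. coli K-12 MG1655 grown on glucose (8 libraries), glycerol (4), xylose (5) or acetate (5). The wild type was sequenced once on each carbon source. Lines evolved on a single carbon source were sequenced on that source: Glc1, Glc2 and Glc3 on glucose, Gly1 and Gly2 on glycerol, Xyl1, Xyl2 and Xyl3 on xylose, and Ac2 and Ac3 on acetate. A further 4 strains came from evolution on alternating sources and were sequenced once on each of their sources: Glc/Gly Generalist, Glc/Xyl Generalist, Glc/Ac Glc Specialist and Glc/Ac Ac Specialist. The wild type on each source and each alternating strain on each source stood alone, so these groups had no replicate check of their own. The labels do not state that lines were grown as separate cultures, so p-values measure the spread between these samples, which may in part be technical. Depth, estimated from the deposited confidence limits, was 1461482 fragments in Ac3, 5696470 in Glc3 and 3749068 at the median. The median FPKM ranged from 6.86 in Glc/Ac Glc Specialist on acetate to 52.7 in Glc2.

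The libraries fell into a pair of sets that the labels do not name. In 7 of them (Glc1, Glc2, Glc3, Gly1, Gly2 and Glc/Ac Glc Specialist on both sources, the first library set) the median FPKM of protein genes shorter than 200 nt was 4.29 to 9.94 times that of genes of 900 nt or more. In the other 15 (the second library set) this ratio was 0 to 0.292. Of the protein genes of at least 100 and under 200 nt, 29.8% to 52.9% were listed at 0 in libraries of the second set and 7.69% to 34.6% in those of the first. No library of the first set is from the wild type or was grown on xylose, and values within the second set are therefore given beside the pooled ones.

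Genes for the use of each carbon source were read first, since they check the labels. All 5 xylose libraries had xylA, xylose isomerase, at 12.38 to 12.84 on the log2(scaled FPKM + 1) scale, against 3.09 to 4.38 in the 8 glucose libraries, and xylF, the xylose-binding protein, at 10.21 to 11.64 against 0.58 to 2.72. All 5 acetate libraries had aceA, isocitrate lyase, at 12.70 or more and acs, acetyl-CoA synthetase, at 8.09 to 9.88, above the highest values of 11.56 and 7.22 on any other source. On the MG1655 chromosome (RefSeq assembly ASM584v2, 1-based), xylA (b3565) lies at 3729443 to 3730765, xylF (b3566) at 3731131 to 3732123, aceA (b4015) at 4217109 to 4218413 and acs (b4069) at 4285413 to 4287371. The gene ptsG (b1101) lies at 1157869 to 1159302, glpK (b3926) at 4115714 to 4117222, glpF (b3927) at 4117245 to 4118090 and glpD (b3426) at 3562013 to 3563518. The genes of glycerol use went against 2 labels. In the library labelled Glc1 on glucose, glpK (glycerol kinase) stood at 10.38, glpF (glycerol facilitator) at 9.64, glpD (glycerol 3-phosphate dehydrogenase) at 10.51 and ptsG (glucose permease) at 7.54, the lowest ptsG of the glucose libraries. In the library labelled Gly2 on glycerol glpK stood at 3.55, glpF at 2.60, glpD at 2.24 and ptsG at 10.46, the highest ptsG of the glycerol libraries. Glc/Gly Generalist on glucose also had glpK at 8.98, glpF at 7.47 and glpD at 10.81. The library labelled Glc/Gly Generalist on glycerol had xylA at 13.06 and xylF at 11.68 together with glpD at 11.36, so its xylose genes went against its label. Other genes that were always read varied within sources. The porin gene ompF was 6.90 in Ac3 and 10.33 to 13.63 elsewhere. The flagellin gene fliC was 11.04 in the wild type on glucose, 10.48 in Xyl1 and 10.60 in Xyl2 and at most 7.28 elsewhere. The glutamate decarboxylase gene gadB was 7.39 to 11.92 in the wild type and 11.09 in Ac3 and at most 4.72 elsewhere. The ranges over all sources were 6.36 to 11.47 for pck (PEP carboxykinase), 1.78 to 6.21 for pyrE and 4.72 to 6.99 for rph.

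**Figure D1:**
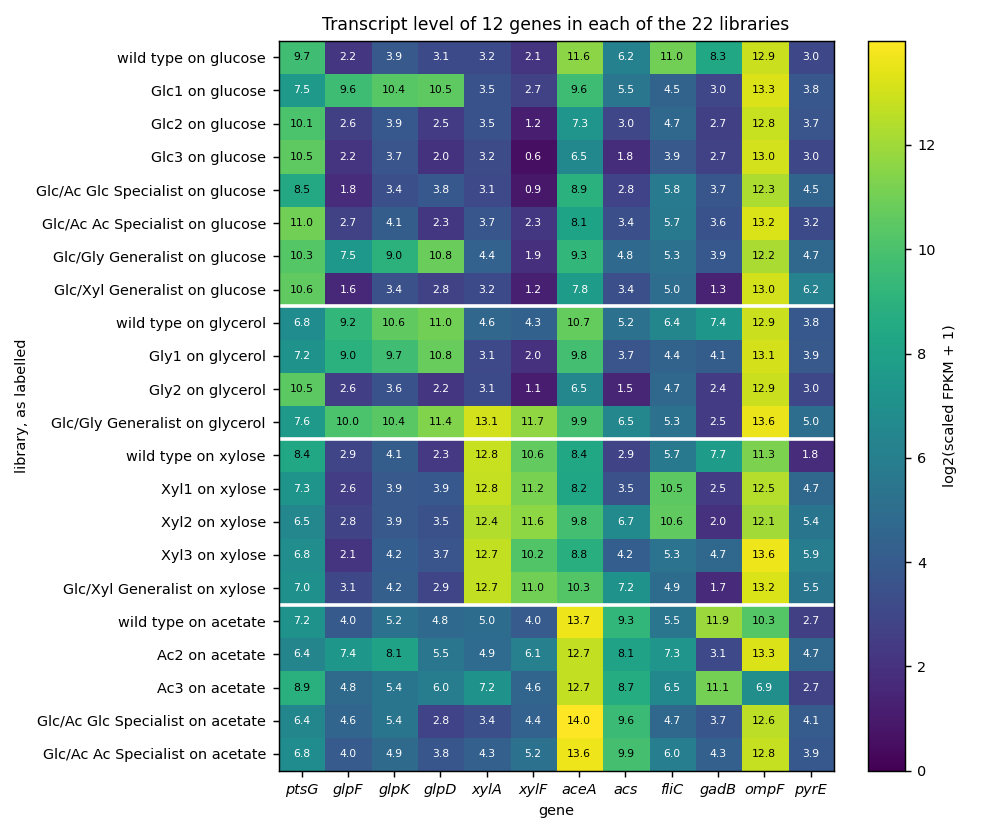
Each row is a library as labelled, each column a gene, and the colour and number give log2(scaled FPKM + 1), with white lines between the carbon sources (glucose, glycerol, xylose, acetate from the top). The library labelled Glc1 on glucose has glpK at 10.38, the one labelled Gly2 on glycerol has it at 3.55, and the one labelled Glc/Gly Generalist on glycerol has xylA at 13.06.

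The first question was how transcript levels on the other sources differ from those on glucose once strain class is accounted for. On acetate, the lists of acetate uptake and the glyoxylate shunt, the TCA cycle, gluconeogenesis and iron uptake were higher than on glucose with a preset correlation, and those of glycolysis, amino acid synthesis and anaerobic respiration were lower (5 acetate against 8 glucose libraries). Of the 15 lists that passed, 0 did so with an estimated correlation, and in some of them fewer than all genes moved. Transcripts of acs rose by 5.58 ± 0.89 (log2, SE, adjusted p = 0.000954), those of the acetate permease gene actP by 5.05 ± 0.67 (adjusted p = 0.000275) and those of aceA by 4.71 ± 0.73 (adjusted p = 0.00079). The largest rises also held entC, the first enzyme of enterobactin synthesis, at 5.69 ± 1.04, and glcE of glycolate oxidation at 5.56 ± 1.08. Also among them were nrdH and nrdI, which serve a ribonucleotide reductase, at 5.92 ± 0.86 and 5.49 ± 0.83, and yjjZ, of unknown function, at 5.97 ± 0.96. The largest falls were those of the small RNA fnrS (-9.25 ± 1.95), which is induced without oxygen, of the short gene azuC (-9.04 ± 2.33) and of the small RNA spf (-8.74 ± 1.58), which represses the use of other sugars. The genes ydfZ (-6.31 ± 1.25), grcA (-5.40 ± 0.81) and blr (-4.75 ± 1.21) fell as well. In limma 735 of 4214 genes passed, 395 higher and 340 lower.

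All 7 genes of the glyoxylate shunt and acetate uptake rose on acetate (7 adjusted over the list alone, median log2 difference 4.71). All 22 iron uptake genes rose (22 adjusted over the list alone, median 3.44), among them fes (5.06 ± 0.95) and fhuF (4.80). Of 16 TCA cycle genes 10 rose (14 adjusted over the list alone), with sucA at 2.78 ± 0.63 and sucC at 2.96 ± 0.67. Of 26 genes for transport of other carbon sources 16 rose (16 adjusted over the list alone), with lsrA of autoinducer uptake at 4.69 ± 0.44 and tnaA, tryptophanase, at 5.43 ± 1.13. Of 21 general stress genes 10 rose (13 adjusted over the list alone), with katE, a catalase, at 2.26 ± 0.44 and osmC at 2.31 ± 0.46. Of 7 arabinose genes 5 rose (5 adjusted over the list alone), with araF at 2.64 ± 0.53, and of 7 xylose genes xylF alone rose (1 adjusted over the list alone). Of 6 genes of gluconeogenesis ppsA (2.80 ± 0.68), maeB (2.43 ± 0.44) and maeA (1.06) rose and glpX fell by 1.22 (4 rises and 1 fall adjusted over the list alone). Of 11 acid resistance genes 0 passed in limma, over all genes or adjusted over the list alone. These 9 lists were higher than the other genes with a preset correlation, at adjusted p from 6.86e-15 (iron uptake) to 0.0192 (gluconeogenesis), and each call was lost with adjusted p = 0.315 to 0.655 with an estimated correlation.

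Lower on acetate were 12 of 13 arginine and glutamate synthesis genes (13 adjusted over the list alone), with argF at -2.21 ± 0.51. So were 13 of 20 histidine and branched-chain amino acid genes (15 adjusted over the list alone), with hisG at -3.39 ± 0.74 and ilvM at -3.51 ± 0.86. Of 12 glycolysis genes 7 fell (10 adjusted over the list alone), with gpmM, a phosphoglycerate mutase, at -3.83 ± 0.64 and gapA at -1.62 ± 0.36. The gene of the other phosphoglycerate mutase, gpmA, rose by 1.06 ± 0.35. Of 7 glucose and mannose uptake genes 3 fell (7 adjusted over the list alone), with ptsG at -2.55 ± 0.71. Of 22 genes of anaerobic respiration and fermentation 6 fell (8 adjusted over the list alone), with dmsA at -3.92 ± 0.87 and nirD at -3.82 ± 0.93. Of 54 ribosomal protein genes 5 fell (0 adjusted over the list alone), with rpmJ at -2.03, a difference that was -0.62 (adjusted p = 0.126) with a term for the library set and -0.52 (adjusted p = 0.462) within the second set. These 6 lists passed at adjusted p from 3.47e-09 (ribosomal proteins) to 0.00126 (glucose and mannose uptake) and each call was lost with adjusted p = 0.315 to 0.487 with an estimated correlation. Of 3 acetate formation genes poxB rose by 1.68 ± 0.50 and ackA fell by 1.66 ± 0.49, and the list did not pass (adjusted p = 0.54). Nor did galactose uptake, of which 3 of 4 genes rose (median 3.51, adjusted p = 0.098).

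Within the second library set (4 acetate and 4 glucose libraries) 60 genes passed for acetate, 57 of them shared with the 735. The differences there were 5.25 ± 0.98 for actP, 4.19 ± 0.92 for aceA (adjusted p = 0.0597) and 5.21 ± 1.24 for acs (adjusted p = 0.08). With a term for the library set 245 genes passed. FPKM as deposited moved the median of all genes by -0.73 for acetate and -0.75 for xylose against glucose and gave 169 higher and 1325 lower genes for acetate. Of the 64 named genes past the threshold 6 stayed past it within the second set and 28 with the term for the set, acs and aceA among the latter. Those given here that lost their calls with the term were blr (-2.59 ± 1.05, adjusted p = 0.169), azuC (-6.57, adjusted p = 0.158), ilvM (-2.17), rpmJ, ppsA (2.42 ± 0.82, adjusted p = 0.1), maeA (0.86), glpX (-1.17), gapA (-1.19), fhuF (3.42), sucA (2.64), hisG (-3.12), argF (-2.06), nirD (-3.93), ptsG (-2.48), poxB (1.64), ackA (-1.51) and xylF (3.05). Within the second set yjjZ, nrdH, nrdI, actP and lsrA were the ones given here that kept theirs, and blr stood at -2.86 (adjusted p = 0.41). Leaving out 1 library also ended calls. The call of glpX was lost in 16 of 22 such fits and had an adjusted p of 0.144 and a difference of -0.93 without Glc/Ac Ac Specialist on glucose, without which ptsG had one of 0.0701 (-2.19). Without Glc/Ac Ac Specialist on acetate ackA had an adjusted p of 0.0964 (-1.31), and without Ac2 xylF one of 0.0542 (3.29). Without Ac3 the adjusted p was 0.0562 for azuC (-7.92), 0.0562 for maeA (0.98), 0.0853 for poxB (1.03) and 0.0984 for rpmJ (-1.63). Acid resistance did not pass without Ac3 (median 0.38, adjusted p = 0.426) or without the wild type on acetate (1.45, adjusted p = 0.0505). Gluconeogenesis did not pass without Ac2 (1.10, adjusted p = 0.0529) or without Glc/Ac Glc Specialist on acetate (1.27, adjusted p = 0.0808) or on glucose (1.27, adjusted p = 0.0809). Ribosomal proteins moved from -0.92 to -0.55 without Ac3, and anaerobic respiration from -1.69 to -1.09 without Glc/Ac Ac Specialist on glucose.

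On xylose all 7 genes of xylose uptake and breakdown rose against glucose (7 adjusted over the list alone, 5 xylose against 8 glucose libraries), with a median log2 difference of 7.99. Transcripts of xylF rose by 9.98 ± 1.01 (SE, adjusted p = 3.09e-05), xylA by 9.71 ± 0.94 (adjusted p = 2.67e-05) and xylE, a xylose-proton symporter, by 8.67 ± 0.86. Those of xylG, xylB and xylH rose by 7.99 ± 0.75, 7.38 ± 0.66 and 7.24 ± 0.70. The largest falls were those of ytjA (-4.27 ± 0.89), yccJ (-2.95 ± 0.50, adjusted p = 0.009) and yhcN (-2.79 ± 0.52). The genes yjiG (-2.18 ± 0.47), wrbA, an oxidoreductase of the general stress response and neighbour of yccJ (-2.18 ± 0.46, adjusted p = 0.0435), and yqgA (-1.99 ± 0.40) fell too. In limma 23 genes passed, 13 higher and 10 lower, and FPKM as deposited gave 14 higher and 464 lower. The xylose list held with an estimated correlation (adjusted p = 0.0129). Iron uptake was higher (median 2.18, 0 of 22 genes over all genes, 18 adjusted over the list alone, adjusted p = 3.31e-16) but had adjusted p = 0.619 with an estimated correlation. General stress (median -0.93, 1 of 21 genes fell, 1 adjusted over the list alone) and glucose and mannose uptake (median -1.23, 0 of 7 genes, 5 adjusted over the list alone) were lower at adjusted p = 3.35e-07 and 1.65e-05. They had adjusted p = 0.652 and 0.619 with an estimated correlation. Also past the threshold were ribosomal proteins (median -0.56), glycerol genes (-1.10), methionine and sulfur assimilation (0.93), flagella and chemotaxis (1.33) and arabinose genes (0.51, and -0.10 with FPKM as deposited or -0.02 with a term for the library set), which had adjusted p = 0.722 to 0.735 with an estimated correlation.

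Within the second library set 6 genes passed for xylose against glucose, all shared with the 23, with xylA at 9.77 ± 1.23 and xylF at 9.73 ± 1.14. There 0 of the 6 falls kept their calls, nor did any with a term for the set, but most stayed large. In the second set and with the term, yqgA stood at -2.06 and -1.98, wrbA at -2.45 and -2.17, yhcN at -2.33 and -2.42, yccJ at -2.38 ± 0.66 (adjusted p = 0.814) and -2.12, yjiG at -1.74 and -1.39 and ytjA at -2.79 and -2.93. In that set flagella and chemotaxis had a median of -0.98 in place of 1.33, and ribosomal proteins 0.06 in place of -0.56. Calls of 3 of the 9 lists ended without single libraries. These were flagella and chemotaxis without Xyl2 (0.54, adjusted p = 0.0531), glycerol genes without the library labelled Glc1 (-0.32, adjusted p = 0.178) or the wild type on xylose (adjusted p = 0.0608), and arabinose genes without the wild type on glucose (0.37, adjusted p = 0.108) or on xylose (0.61, adjusted p = 0.0608) or without Xyl2 (0.51, adjusted p = 0.0531). The count was 13 without Glc2 and 15 without the library labelled Glc1, and without the latter 17 lists passed in place of 9. Leaving out 1 library ended the calls of 5 falls at nearly equal differences. These were yqgA (-1.92, adjusted p = 0.107) and yjiG (-1.96, adjusted p = 0.172) without Xyl3, wrbA (-1.97, adjusted p = 0.135) and yhcN (-2.53, adjusted p = 0.0677) without Xyl2, and ytjA (-4.02, adjusted p = 0.119) without Glc2.

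On glycerol, 0 genes passed against glucose in limma over the 4 glycerol and 8 glucose libraries as labelled, and 70 had an unadjusted p under 0.05. The smallest p-values were those of yohO (5.97 ± 1.18, adjusted p = 0.532) and of yaiZ, nemR, yjhE and ydfX (adjusted p = 0.998). Of 12 glycerol genes 0 passed (0 adjusted over the list alone). Their median of 2.46 set them above other genes with a preset correlation (adjusted p = 1.59e-09), as did that of the xylose genes (1.76, adjusted p = 3.24e-08). Both had adjusted p = 0.479 with an estimated correlation. A further 7 lists passed with the preset correlation: transport of other carbon sources (median 0.60), NADH dehydrogenase I (0.44), heat shock (0.50), methionine and sulfur assimilation (-0.76), arginine and glutamate synthesis (-0.50), glucose and mannose uptake (-0.41) and iron uptake (-0.31), each with adjusted p = 0.886 with an estimated correlation. Without the libraries labelled Glc1 on glucose and Gly2 on glycerol, 8 genes passed: glpF, glpT, glpK, glpD, glpQ, ybhQ and galS rose and ptsG fell. Both libraries were left out after seeing their glp and ptsG levels, so the refit is no test of those genes. The same holds without the library labelled Glc/Gly Generalist on glycerol as well, where 9 genes rose, 8 of them in the glycerol list, whose median was then 6.50 while that of the xylose list was 0.28. Inside the second library set 0 genes passed in limma (glycerol list median 4.32), within the first set ypdK and yohO passed, and without the wild type on glycerol 1 gene. Each of the 9 medians moved by over 1.5 times without some single library, that of the glycerol genes to 0.83 without the wild type on glycerol and that of the xylose genes to 0.01 without Glc/Gly Generalist on glucose. The calls of 7 ended in this way, those of the glycerol genes and NADH dehydrogenase I excepted. The iron uptake median was 0.14 within the second set and 0.12 without the wild type on glucose.

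The next question was how lines evolved on a single source differ from the wild type. Over all 4 sources, the lists of acid resistance, general stress, and curli and fimbriae were lower in the evolved lines with a preset correlation (10 lines against 4 wild type libraries), although 0 of their genes passed over all genes. With an estimated correlation the call of curli and fimbriae held and those of acid resistance and general stress did not. The acid resistance list had a median of -3.42, with 0 of 11 genes past the threshold over all genes and 10 adjusted over the list alone (adjusted p = 1.39e-13). It had adjusted p = 0.327 with an estimated correlation. In single lines its median ran from -6.80 to 0.27, with 9 of 10 lines below the wild type on the same source and Ac3 above it. Lines on a source share 1 wild type library, so such counts of lines are not independent. General stress had a median of -1.24 (0 of 21 genes, 10 adjusted over the list alone, adjusted p = 2.55e-10, and 0.402 as adjusted p with an estimated correlation), again below the wild type in 9 of 10 lines and above it in Ac3. Curli and fimbriae, with a median of -1.21 (0 of 14 genes, 9 adjusted over the list alone, adjusted p = 1.17e-08), lay below the wild type in 10 of 10 lines, by -2.55 to -0.15, and held with an estimated correlation (adjusted p = 0.0215). Within the second library set these medians were -3.13, -1.45 and -1.41.

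**Figure D2:**
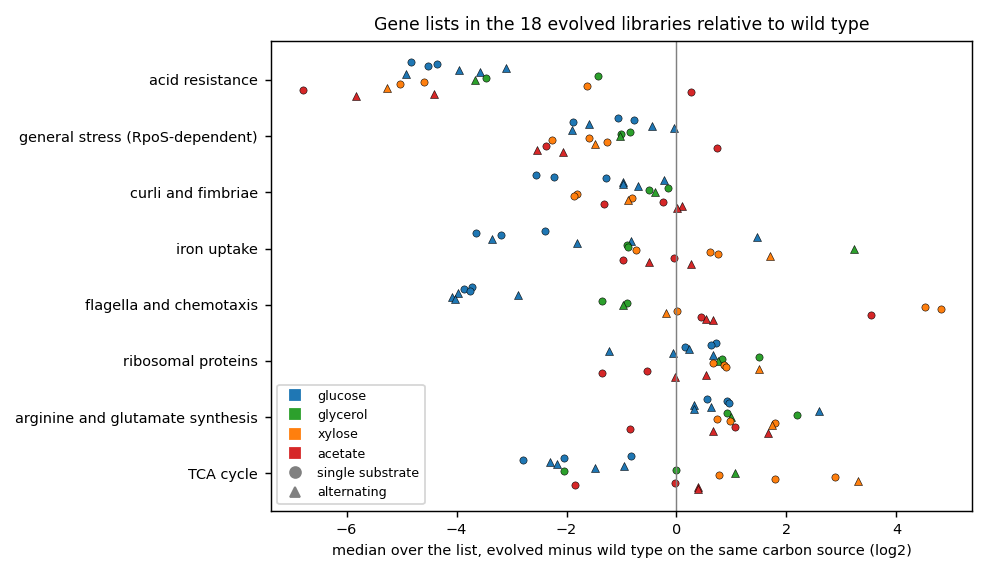
Each point is 1 of the 18 evolved libraries, and the horizontal axis gives the median over a gene list of its log2 difference from the wild type on the same carbon source, with circles for single-substrate lines, triangles for alternating strains and colours for the source. Curli and fimbriae lie at -2.55 to -0.15 in the 10 single-substrate lines and acid resistance at -6.80 to 0.27.

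For the lines over all sources, iron uptake (median -1.17, below the wild type in 8 of 10 lines) and the glyoxylate shunt (-0.99) were also lower. Higher were ribosomal proteins (0.45), arginine and glutamate synthesis (0.92, above the wild type in 9 of 10 lines, 5 genes adjusted over the list alone) and histidine and branched-chain amino acid synthesis (0.49, 1 gene adjusted over the list alone). These 5 lists passed at adjusted p from 3.37e-07 to 0.0343 and had adjusted p = 0.679 to 0.988 with an estimated correlation. Without the wild type on glucose the medians of the glyoxylate shunt, iron uptake and histidine and branched-chain amino acid synthesis were -0.15, -0.50 and 0.19, and the call of the glyoxylate shunt ended there and in 7 other such fits. Without the wild type on glycerol the calls of ribosomal proteins (0.22, adjusted p = 0.0754), histidine and branched-chain amino acid synthesis (0.20, adjusted p = 0.367) and arginine and glutamate synthesis (0.77, adjusted p = 0.0703) ended as well. In libraries of the second set, again with lines on xylose and acetate only, the median of ribosomal proteins was -0.16. That of histidine and branched-chain amino acid synthesis was -0.10 there. As to single genes, limma called 0 of 4214, with 538 at an unadjusted p under 0.05. The smallest p-values, all at adjusted p = 0.0657, were those of yrdF (6.53 ± 1.18), a copy of insA (1.62 ± 0.31), mlaB (a rise), yghA (-1.65 ± 0.31) and the alcohol dehydrogenase gene adhP (-2.36 ± 0.44). The count was 176 without Ac3, 11 without the wild type on xylose and 1 without Xyl2, and without the wild type on xylose 13 lists passed in place of 8. The terminal oxidase and e14 prophage lists passed in no comparison made here, with medians of 0.44 and -0.12 in this one.

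On glucose, the wild type library had transcripts of zinT, a periplasmic zinc-binding protein (b1973, 2041375 to 2042025), at 20191 scaled FPKM, against 2.79 in the library labelled Glc1, 2.42 in Glc2 and 6.63 in Glc3 (log2 difference -12.09 ± 0.71, adjusted p = 2.82e-05). Its level of ykgO, a ribosomal protein paralog made when zinc is short, was 1408 against 18.5, 0 and 0 (adjusted p = 0.0437). The ferric iron uptake genes fepD (-3.42 ± 0.64, adjusted p = 0.0262) and fhuA (-3.81 ± 0.72, adjusted p = 0.0271) fell. Of 22 iron uptake genes 2 fell (20 adjusted over the list alone, median -3.11, adjusted p = 2.91e-13), and the list had adjusted p = 0.734 with an estimated correlation. The short genes ilvX, mgtL, pheL and chiX, at 5632, 3044, 2051 and 565 scaled FPKM in the wild type, were listed at 0 in the 3 lines. Conversely, yneM, shoB, ypdK, tisB, dinQ and cbdX were listed at 0 in the wild type. The ribosomal protein genes rpmH (4.12 ± 0.36), rpmJ (3.83), rpmE (3.46) and rpmD (2.76) rose, 8 of 54 in that list (10 adjusted over the list alone, median 0.61, which quantile normalization turned to -0.21). The list passed at adjusted p = 0.000237 and had adjusted p = 0.916 with an estimated correlation. In limma 138 genes passed, 102 higher and 36 lower, of which 73 are shorter than 300 nt. The median difference of the 129 protein genes under 200 nt was 2.62. The wild type on glucose is in the second library set and the 3 lines are in the first. The glucose libraries of Glc/Ac Ac Specialist, Glc/Gly Generalist and Glc/Xyl Generalist share the set of the wild type. For 52 of the 138 genes all 3 lay nearer to the lines than to the wild type, so the library set alone does not account for these. They include zinT (7.32 to 15.5 scaled FPKM), ykgO (at most 24.2) and ilvX, mgtL, pheL and chiX (listed at 0). For 44 genes all 3 lay nearer to the wild type, among them rpmH, rpmJ, rpmE, rpmD, shoB, ypdK, tisB, dinQ and cbdX, and for 42 they were divided, among them yneM, fepD and fhuA. For both of these groups line and set cannot be told apart.

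Other lists past the threshold on glucose were flagella and chemotaxis (median -3.76), TCA cycle (-1.93), acid resistance (-4.64), glyoxylate shunt (-2.73), purine synthesis (-0.97) and general stress (-1.44), lower, and anaerobic respiration (2.75, 8 of 22 genes adjusted over the list alone), higher, all with adjusted p = 0.916 with an estimated correlation. Curli and fimbriae (-2.04, 4 falls and 1 rise adjusted over the list alone) had adjusted p = 0.329 with an estimated correlation. In the 3 evolved libraries in the set of the wild type, medians against it lay nearer to the lines for flagella and chemotaxis (-4.08 to -2.89), acid resistance (-4.92 to -3.57), the glyoxylate shunt (-2.76 to -1.40) and anaerobic respiration (2.46 to 4.39), so the set alone does not account for these. They were nearer to 0 for curli and fimbriae (-0.98 to -0.70) and divided for the other 5 lists, where line and set cannot be told apart. The gene count was 78 without Glc2, 367 without Ac2 and 368 without Ac3. Of the 138 genes 39 were protein genes of 600 nt or more, and a refit on genes of that length alone called 16. General stress lost its call without Glc3 (-0.92, adjusted p = 0.0527) and without the library labelled Glc1 (-1.63, adjusted p = 0.0519). Calls also ended at nearly equal differences for fepD (-3.24, adjusted p = 0.086) and rpmD (2.65, adjusted p = 0.0685) without Glc2, and fhuA (-3.63, adjusted p = 0.0774) without Glc3. The adjusted p of ykgO, at 18.5 and 0 in the lines left, was 0.122 without Glc2.

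On glycerol the wild type had higher levels of ygfK, an oxidoreductase subunit (difference -3.61 ± 0.39, adjusted p = 0.00325, Gly1 and the library labelled Gly2 against 1 wild type library), yniA (-2.95 ± 0.37), ydcJ (-3.45 ± 0.61), yqfA (-3.32 ± 0.52), ssnA (-3.05 ± 0.49) and patD (-2.64 ± 0.49). The lines had higher levels of purE, of purine synthesis (3.83 ± 0.72, adjusted p = 0.0326), ilvC, of branched-chain amino acid synthesis (2.65 ± 0.53, adjusted p = 0.0432), and the short ribosomal protein genes rpmG (3.60), rpmD (3.41), rpmH (3.32) and rpmJ (3.31). The short genes yneM, shoB, dinQ, tisB, pmrR and cbdX were listed at 0 in the wild type. Ribosomal proteins rose in 9 of 54 genes (24 adjusted over the list alone, median 1.28, adjusted p = 7.94e-14, and adjusted p = 0.731 with an estimated correlation). Histidine and branched-chain amino acid synthesis rose in 1 of 20 (8 adjusted over the list alone, median 1.84, adjusted p = 2.65e-06), with adjusted p = 0.156 with an estimated correlation. Glycerol genes had a median of -4.07 (adjusted p = 0.00128, and adjusted p = 0.731 with an estimated correlation), with -6.84 in the library labelled Gly2 and -1.42 in Gly1, and without the former the list did not pass. Ribosomal proteins had a median of 0.83 without Gly1. Another 12 lists passed, with adjusted p = 0.731 to 0.83 with an estimated correlation. In limma 95 genes passed, 80 higher and 15 lower, 48 of them shorter than 300 nt. The wild type and the lines were in different library sets, which cannot be told apart from these differences, as the 1 evolved glycerol library in the set of the wild type is the doubted one labelled Glc/Gly Generalist.

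Without the library labelled Gly2 the glycerol count was 32 and without Gly1 45. Without the library labelled Gly2 calls ended at nearly equal differences: ssnA (-2.99, adjusted p = 0.106), yqfA (-3.30, adjusted p = 0.0968), ydcJ (-3.12, adjusted p = 0.137), patD (-2.41, adjusted p = 0.158), ilvC (2.74, adjusted p = 0.145) and purE (3.72, adjusted p = 0.146). Without Gly1 rpmD was at 2.95 (adjusted p = 0.0538). Leaving out 1 library ended the calls of 9 of the 15 lists, though not those of ribosomal proteins or of histidine and branched-chain amino acid synthesis. The count was 63 without the library labelled Glc1, 61 without Glc2, 59 without Glc3, 49 without Xyl2, and 266 without Ac2 or without Ac3.

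On xylose, where the 4 libraries compared are all in the second set, the lines had less uspC, a universal stress protein (25.7, 36.9 and 31.9 scaled FPKM in Xyl1, Xyl2 and Xyl3 against 296.2 in the wild type, log2 difference -3.21 ± 0.36, adjusted p = 0.0327) and less ydiU (35.2, 46.5 and 35.0 against 274.2, -2.80 ± 0.34, adjusted p = 0.0327). The short genes cspI and ybfI were listed at 0 against 131.9 and 32.6 in the wild type. These 4 genes were all that limma called, and 610 had an unadjusted p under 0.05. With the preset correlation 12 lists passed, 7 higher and 5 lower, among them ATP synthase (median 2.22, 0 of 9 genes, 8 adjusted over the list alone, adjusted p = 1.86e-05), flagella and chemotaxis (3.12, adjusted p = 7.56e-06) and acid resistance (-4.07, adjusted p = 0.00252). All 12 had adjusted p = 0.559 to 0.924 with an estimated correlation. The count was 1 without the library labelled Glc1, Glc2, Glc3, Xyl1 or Xyl2, 23 without Xyl3, 100 without Ac2 and 101 without Ac3. At nearly equal differences ydiU lost its call without Xyl1 (-2.73, adjusted p = 0.141) and uspC without Xyl2 (-3.32, adjusted p = 0.116), as did cspI, at 0 in the lines left, without Xyl1 (adjusted p = 0.141). Flagella and chemotaxis had a median of 4.70 without Xyl3. Calls of 3 of the 12 lists ended without some single library: glucose and mannose uptake, transport of other carbon sources and pyrimidine synthesis. With the libraries of the second set alone 0 of these 4 calls held, again at nearly equal differences: uspC (-3.21 ± 0.37) had an adjusted p of 0.115, ydiU (-2.80 ± 0.34) 0.138, cspI 0.0748 and ybfI 0.0681.

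On acetate 0 genes passed between Ac2 and Ac3 and the wild type in limma, and 438 had an unadjusted p under 0.05. The smallest p-values (adjusted p = 0.187) were those of the cold shock gene cspB (7.38 ± 1.31), the serine deaminase gene sdaA (2.06 ± 0.34), intK, ydfA and ymgA. Lower lists were led by purine synthesis (median -2.60, 0 of 14 genes, 9 adjusted over the list alone, adjusted p = 1.2e-08), with adjusted p = 0.576 with an estimated correlation. They were followed by ribosomal proteins (-0.91, 0 of 54 genes, 1 adjusted over the list alone) and methionine and sulfur assimilation (-2.39), the last 2 with adjusted p = 0.815 with an estimated correlation. Of 11 lists past the threshold 4 were higher and 7 lower, and all had adjusted p = 0.576 to 0.921 with an estimated correlation. The count was 140 without Ac3, 89 without Ac2, and 1 without Gly1, the library labelled Gly2, Xyl1 or Xyl3, and without Ac2 7 lists passed. Without Ac2 the medians of methionine and sulfur assimilation, acid resistance and general stress turned from -2.39, -2.91 and -0.74 to 0.10, 0.27 and 0.74, and that of NADH dehydrogenase I from 0.48 to -0.26. Without Ac3 those of purine synthesis and ribosomal proteins were -1.66 and -0.53, and these were the 2 of the 11 lists whose calls no left-out library ended.

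Whether the difference between evolved lines and wild type depends on the source was tested directly, and it did for 120 genes, 62 of them shorter than 300 nt. The named ones were short genes or small RNAs listed at 0 in many libraries: yneM (adjusted p = 1.02e-05), shoB and ilvX (9.2e-06), ypdK (1.87e-05), tisB and dinQ (4.88e-05), cbdX and chiX (2.61e-05), mgtL (9.2e-06), pheL (1.02e-05), agrA (2.93e-05) and dsrA (0.000148). The lines on glucose and glycerol, and no other lines, are in the first library set. Source and set therefore cannot be told apart in this test. The 0 of ilvX, chiX, mgtL and pheL in evolved libraries on glucose is usual for genes this short. The count was 473 without Ac2, 387 without Ac3, 58 without Glc2, 66 without Glc3, 75 without the library labelled Gly2, 60 without Xyl1 and 53 without Xyl2, and 16 in a refit on genes of 600 nt or more.

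The remaining comparisons ask how strains evolved on alternating sources differ from lines evolved on a single source, with both libraries of a strain against the 10 lines and source accounted for. In Glc/Gly Generalist rnpA, the protein part of RNase P, fell by 3.17 ± 0.43 on the log2 scale (adjusted p = 0.00851), and its overlapping neighbour yidD by 3.27 ± 0.52 (adjusted p = 0.0119). The gene of rnpA lies at 3884493 to 3884852 and yidD at 3884816 to 3885073, so reads of the overlap may be shared. Levels of rnpA were 56.9 scaled FPKM on glucose and 41.6 on glycerol, those of yidD 30.2 and 45.3. The nucleotide-binding protein gene yajQ (-2.76 ± 0.42), the tRNA modification gene tusC (-2.50 ± 0.46), yhhH (-2.74 ± 0.51) and yneG (-1.97 ± 0.37) also fell. The other 2 of the 8 genes past the threshold were udk, uridine kinase, and rnt, ribonuclease T. All 8 were lower. Higher lists were iron uptake (median 3.04, 0 of 22 genes, 19 adjusted over the list alone, adjusted p = 2.56e-19) and xylose genes (3.76, 0 of 7, 7 adjusted over the list alone, adjusted p = 1.46e-10), both with adjusted p = 0.405 with an estimated correlation. TCA cycle (1.37), methionine and sulfur assimilation (1.55), glyoxylate shunt (1.14), general stress (0.73, and -0.02 with FPKM as deposited) and the pentose phosphate pathway (0.52, and -0.23 with FPKM as deposited) had adjusted p = 0.754 to 0.851 with an estimated correlation. FPKM as deposited moved the median of all genes in this comparison by -0.74.

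Without the library of Glc/Gly Generalist labelled as grown on glycerol, which leaves the strain 1 library, 0 genes passed in limma. The falls of 4 genes were then about as large, at -2.80 for rnpA (adjusted p = 0.324), -3.44 for yidD (adjusted p = 0.324), -2.51 for yajQ (adjusted p = 0.422) and -2.73 for yhhH (adjusted p = 0.798), while tusC was at -1.71. The medians of the xylose, iron uptake and general stress lists were then 0.44, 1.91 and 1.23. Without its glucose library yneG was at -1.31 (adjusted p = 0.665). The count was 15 without its glucose library, 14 without the wild type on glycerol or without Ac2, 13 without Ac3, and 4 or 5 without any 1 of 12 others (the wild type on glucose or acetate, Glc2, Glc3, Gly1, Xyl1, Xyl2, Xyl3, Glc/Ac Ac Specialist on either source, or the library labelled Glc1 or Gly2). Without the library labelled Glc1 12 lists passed, and without Gly1 13, while the calls of xylose genes, glyoxylate shunt, general stress and the pentose phosphate pathway ended without some single library. This strain is in the second library set and all lines on its sources in the first, so strain and set cannot be told apart there. With the second set alone and with a term for the set 0 genes passed in limma. In these fits rnpA stood at -2.55 and -2.63 ± 0.55, yidD at -2.76 and -2.81, yajQ at -2.03 and -2.02, yhhH at -3.53 and -3.63 (adjusted p = 0.094), tusC at -1.62 and -1.60 and yneG at -1.35 and -1.51. Without the library labelled Glc/Gly Generalist on glycerol and the 2 doubted ones, the medians of the iron and xylose lists were 2.04 and 0.52.

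In Glc/Xyl Generalist 0 genes passed in limma and 231 had an unadjusted p under 0.05. The smallest p-values (adjusted p = 0.442) were those of rph (1.53 ± 0.37), the RNase PH gene upstream of pyrE, and of cspE (-2.96 ± 0.69), yhhH, asr and yjhE. With the preset correlation 16 lists passed, 12 higher and 4 lower, led by arginine and glutamate synthesis (median 1.17) and iron uptake (1.36), both at adjusted p = 3.73e-08. They included pyrimidine synthesis (1.82) and flagella and chemotaxis (-1.73), both at adjusted p = 9.71e-07, and outer membrane porins (0.60, adjusted p = 0.0287) and heat shock (0.34, and -0.11 with FPKM as deposited). All 16 had 0 genes past the threshold and adjusted p = 0.708 to 0.719 with an estimated correlation. FPKM as deposited moved the median of all genes by -0.48. Among libraries of the second set flagella and chemotaxis had a median of -3.58 and ribosomal proteins 1.15, against 0.61 over all libraries. Without its xylose library 7 lists passed, and the medians of the glyoxylate shunt and anaerobic respiration turned from 0.82 and -0.96 to -0.46 and 0.03. Without its glucose library general stress turned from -0.64 to 0.29, and without Ac3 1 gene passed. The median of arginine and glutamate synthesis was 0.58 without its glucose library, and those of iron uptake, porins and flagella and chemotaxis were 0.89, 0.97 and -1.11 without its xylose library. That of heat shock was 0.70 without the library labelled Glc1. Calls of 11 of the 16 lists ended without some single library, but not those of arginine and glutamate synthesis, iron uptake and pyrimidine synthesis.

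In both Glc/Ac strains the listed levels of cspC, an abundant member of the cold shock protein family (1907226 to 1907435 on the chromosome), were 0 or far below those of the other strains. In Glc/Ac Glc Specialist cspC was listed at 0 on both sources (adjusted p = 1.09e-08), where reads given to its paralogs are not excluded, while the upstream gene of the same operon, yobF (1907448 to 1907591), stood at 3005 and 2046 scaled FPKM. In Glc/Ac Ac Specialist cspC stood at 15.3 on glucose and 28.2 on acetate (log2 difference -7.87 ± 0.64, adjusted p = 7.91e-06) and yobF at 133.6 and 287.9 (-5.22 ± 0.77, adjusted p = 0.0102). In the other 18 libraries the lowest cspC was 965.8, in Ac2, and the highest 10490.0. In limma cspC was the 1 gene called for Glc/Ac Glc Specialist (398 at an unadjusted p under 0.05), and cspC and yobF were the 2 called for Glc/Ac Ac Specialist (334). Within the second library set cspC differed by -6.96 ± 0.74 in Glc/Ac Ac Specialist (adjusted p = 0.0211), and yobF by -3.96 ± 0.76 with its call lost (adjusted p = 0.966). Without its glucose library the difference of yobF was -3.72 (adjusted p = 0.486) and 1 gene passed, without its acetate library 5 and without Ac2 6. The count for Glc/Ac Glc Specialist was 9 without its glucose library and 2 without its acetate library, the wild type on glycerol, Xyl3 or either library of Glc/Ac Ac Specialist.

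**Figure D3:**
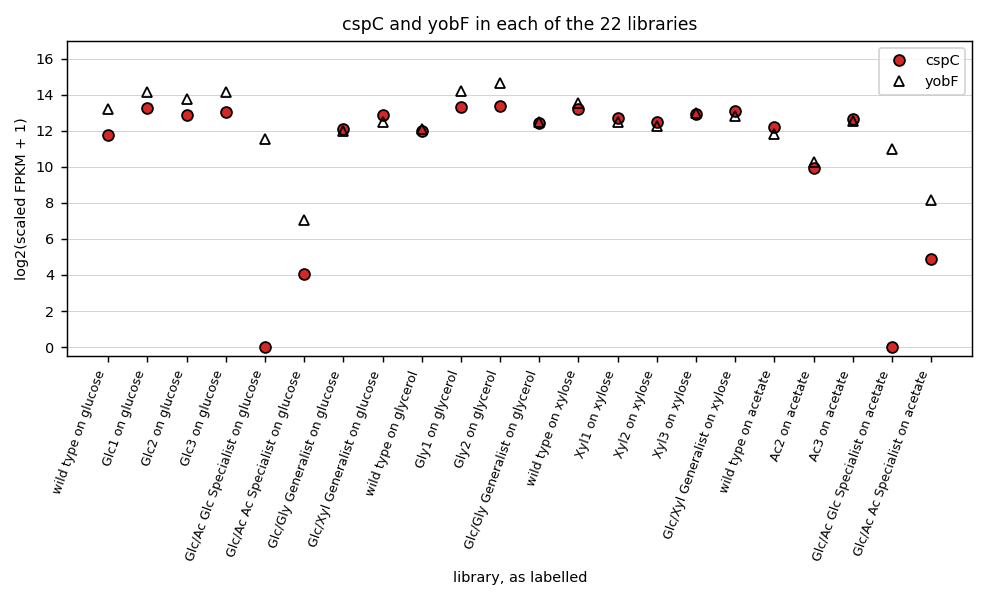
The vertical axis gives log2(scaled FPKM + 1) of cspC (filled circles) and yobF (open triangles) in each of the 22 libraries along the horizontal axis. Transcripts of cspC are listed at 0 in Glc/Ac Glc Specialist on both sources and stand at 15.3 and 28.2 scaled FPKM in Glc/Ac Ac Specialist, against at least 965.8 elsewhere.

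Among the lists, iron uptake was higher in Glc/Ac Glc Specialist (median 2.71, 0 of 22 genes, 14 adjusted over the list alone, adjusted p = 1.34e-15), with adjusted p = 0.652 with an estimated correlation. So were curli and fimbriae (0.99, 6 of 14 adjusted over the list alone, adjusted p = 0.0015, and adjusted p = 0.648 with an estimated correlation), ribosomal proteins (0.38), methionine and sulfur assimilation (1.09) and ATP synthase (0.74), the last 3 with adjusted p = 0.891 with an estimated correlation. With FPKM as deposited, which moved the median of all genes by -1.22, these last 4 had medians of -0.18, -0.99, -0.28 and -0.63. Lower were glycolysis (-0.76), transport of other carbon sources (-0.89), anaerobic respiration (-1.41), flagella and chemotaxis (-0.95) and acetate formation (-1.13), each with adjusted p = 0.891 with an estimated correlation. Both libraries of this strain are in the first set, and with a term for the set flagella and chemotaxis turned to 0.57 and ribosomal proteins to -0.27. For Glc/Ac Ac Specialist ribosomal proteins (-0.67, and -0.02 within the second library set) and arginine and glutamate synthesis (0.69) passed, both with adjusted p = 0.916 with an estimated correlation. Each of the 10 list calls for Glc/Ac Glc Specialist ended without some single library. Without its glucose library 4 lists passed, and iron uptake and anaerobic respiration had medians of 0.18 and -0.64. Without its acetate library ATP synthase had a median of -0.10. Without Ac2 flagella and chemotaxis, transport of other carbon sources and sulfur assimilation stood at -0.37, -0.23 and 0.08, and without Ac3 ribosomal proteins at 0.01. Ribosomal proteins stood at 0.28 for Glc/Ac Ac Specialist without its glucose library, and arginine and glutamate synthesis at -0.20 without its acetate library, where the latter's call ended, as it did without Ac3 (0.20). For Glc/Ac Ac Specialist 11 passed without its glucose library, 8 without its acetate library, Glc3 or Ac2, 6 without the library labelled Gly2, 5 without the wild type on glycerol and 4 without Ac3.

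Set against each other over both sources, the Glc/Ac specialists differed in 0 genes in limma, with 392 at an unadjusted p under 0.05. The smallest p-values were those of cspC (-4.45 ± 0.79, adjusted p = 0.162), yoeH, yhbQ (2.04 ± 0.40), xseB and hyi (adjusted p = 0.179). The count was 3 without Glc/Ac Glc Specialist on glucose, 2 without it on acetate and 1 without Ac2. Of 12 lists past the threshold 3 were higher in Glc/Ac Glc Specialist, ribosomal proteins (median 0.99), iron uptake (2.07) and methionine and sulfur assimilation (1.95). Another 9 were lower, led by glycolysis (-1.29) and anaerobic respiration (-1.87), and all 12 had adjusted p = 0.702 to 0.869 with an estimated correlation. Each of the 12 calls ended without some single library. Lists fell to 3 without Glc/Ac Glc Specialist on glucose, where iron uptake had a median of -0.18. They fell to 1 without Glc/Ac Ac Specialist on glucose, where ribosomal proteins stood at -0.01, sulfur assimilation at -0.24, glycolysis at -0.58 and anaerobic respiration at -0.39. With a term for the library set ribosomal proteins stood at -0.19. Without Glc/Ac Ac Specialist on acetate arginine and glutamate synthesis turned from -0.50 to 0.24. The strains are in different library sets, which cannot be told apart from the strain.

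Whether that difference depends on the source was tested with 1 library in each cell. The iron uptake list had a median of -5.89: its median log2 level was 7.08 in Glc/Ac Glc Specialist and 2.36 in Glc/Ac Ac Specialist on glucose, and 7.37 and 8.37 on acetate, so the sign of the difference turned. Of its 22 genes 0 passed over all genes and 22 adjusted over the list alone (adjusted p = 3.91e-24, and adjusted p = 0.47 with an estimated correlation). The median of anaerobic respiration was 3.43 (adjusted p = 5.5e-09, and adjusted p = 0.77 with an estimated correlation). In limma 10 genes passed, all lower and 9 under 300 nt. Transcripts of yjjZ (-9.40 ± 1.02) stood at 274.1 scaled FPKM in Glc/Ac Glc Specialist and 0 in Glc/Ac Ac Specialist on glucose. They stood at 166.3 and 409.7 on acetate. The others named were ldrC, agrA, shoB, ypdK and dinQ. The strains differ in library set and Glc/Ac Glc Specialist on acetate had the lowest FPKM, which limits this test. The other lists past the threshold were glycolysis (1.92), transport of other carbon sources (1.81), NADH dehydrogenase I (1.14), glucose and mannose uptake (2.19) and the pentose phosphate pathway (0.93), higher. Ribosomal proteins (-0.96), methionine and sulfur assimilation (-3.19) and purine synthesis (-2.22) were lower, and these 8 lists had adjusted p = 0.535 to 0.844 with an estimated correlation. With FPKM as deposited, which moved the median of all genes by -1.84, glycolysis, NADH dehydrogenase I and the pentose phosphate pathway had medians of -0.18, -0.94 and -1.18.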

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

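The tests of whether a difference depends on the carbon source were fixed before the data were examined, while the counts of short genes and the rRNA shares given here were chosen only after the result was seen. No group held 4 to 10 samples, so no sample was tested for standing apart from its group.

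The difference between single-substrate lines and wild type differed between carbon sources in 120 genes by a test of the difference itself (limma), of which 62 were shorter than 300 nt. Source and library set cannot be told apart there, as lines on glucose and glycerol and no others are in the first set.

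The Glc/Ac specialist difference differed between acetate and glucose in 10 genes, 9 under 300 nt. It rests on 1 library per cell, 1 with the lowest FPKM, and strains of different library sets. Of 30 lists 10 passed with the preset correlation and 0 with an estimated one.

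Reads of rRNA genes, which the comparisons leave out, made up 4.86% of the FPKM weighted by gene length in Glc/Ac Glc Specialist on acetate, against at most 0.159% in the wild type.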

How the results depend on the processing

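The alternatives without the doubted libraries, with genes of 600 nt or more, with a term for the library set, or with 1 library set alone were chosen after seeing the data, and the others were fixed before. A count-based test was not run, as the files hold FPKM. Depth limits what can be seen: 1461482 fragments in Ac3 and deposited limits of 15.2% to 44.7% of the value for genes of 20 to 50 FPKM leave small changes of low genes undetectable. The lone libraries are assumed to vary like the lines of a group. Of the named genes past the threshold 0 reversed in any alternative, while medians of some lists turned. Where no reason is given below for a change, the cause was not tested.

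FPKM as deposited gave 1494 genes for acetate against glucose (735 with scaling), 478 for xylose (23), 224 for evolved lines against wild type on glucose (138) and 1 on xylose (4), 18 for Glc/Gly Generalist (8), 1229 for Glc/Ac Glc Specialist (1) and 26 for the test of whether the specialist difference depends on the source (10). Without scaling the median of all genes moved by -0.73 for acetate and -1.22 for Glc/Ac Glc Specialist. Quantile normalization gave 58 genes for evolved lines on glycerol (95), 17 on xylose (4) and 5 for Glc/Gly Generalist (8). A pseudocount of 0.1 gave 24 genes for evolved lines on xylose, 8 on acetate (0), 1 between the specialists (0) and 22 for the dependence of their difference on the source. A pseudocount of 10 gave 15 for evolved lines on xylose and 4 for Glc/Gly Generalist. A mean of at least 10 FPKM, which tests fewer genes, gave 63 for evolved lines on glycerol, 15 on xylose, 13 for Glc/Gly Generalist and 4 for the dependence of the specialist difference. With rRNA and tRNA genes kept, 1 gene passed for evolved lines on acetate, 14 for Glc/Ac Glc Specialist, 14 between the specialists and 20 for the dependence of their difference.

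With only strains on 2 or more carbon sources 8 genes passed for acetate and 0 for xylose. With the single-substrate evolved lines alone 3 passed for glycerol (0 over all libraries), namely ypdK, yohO and a copy of insI1, and 173 for xylose. The line number as a replicate block in that set gave 2 for glycerol and 126 for xylose. Over all libraries the replicate block gave 649 genes for acetate, 18 for xylose and 4 for Glc/Gly Generalist. Across sources, same-numbered lines correlated at -0.197 to 0.642 (12 pairs) and others at -0.642 to 0.601 (25 pairs). Sources with 2 lines give mirrored values, so whether same-numbered lines are related is open. With only the 2 substrates of the strain, 125 genes passed for Glc/Gly Generalist and 1 for Glc/Ac Ac Specialist (2).

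Without the libraries labelled Glc1 on glucose and Gly2 on glycerol, left out for their glp and ptsG levels, 8 genes passed for glycerol (6 of them glp genes or ptsG, which the choice itself brings about), 15 for xylose, 34 for evolved lines on glycerol, 4 on acetate and 0 for Glc/Gly Generalist. The lists past the threshold then were 14 for glycerol (9), 14 for xylose (9) and 7 for Glc/Ac Ac Specialist (2). Without those 2 and Glc/Gly Generalist on glycerol, 9 genes passed for glycerol, 13 for xylose, 36 for evolved lines on glycerol, 4 on acetate, 4 for Glc/Gly Generalist and 1 for Glc/Ac Ac Specialist, and 17 lists for xylose.

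In a refit on genes of 600 nt or more alone, which leaves out cspC and yobF by length, 13 passed for xylose, 16 for evolved lines on glucose (39 protein genes of that length over all genes), 16 on glycerol (29), 0 on xylose, 16 for the dependence of the evolved difference on the source (120), 3 for Glc/Gly Generalist, 0 for Glc/Ac Glc Specialist, 0 for Glc/Ac Ac Specialist and 0 for the dependence of the specialist difference. Lists were then 14 for xylose, 10 for Glc/Xyl Generalist (16) and 0 for Glc/Ac Ac Specialist. A term for the library set gave 245 genes for acetate, 12 for xylose, 0 for Glc/Gly Generalist and 1 between the specialists, and 13 lists for Glc/Gly Generalist (7) and 7 for Glc/Ac Ac Specialist. Only the 15 libraries of the second set, which are fewer samples, gave 60 genes for acetate, 6 for xylose, 1 for evolved lines on acetate, 0 for Glc/Gly Generalist and 1 for Glc/Ac Ac Specialist, and 14 lists for glycerol and 5 for Glc/Ac Ac Specialist. The 7 libraries of the first set gave 2 genes for glycerol.

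With an estimated correlation in camera, 1 list passed for xylose and 1 for evolved lines against wild type over all sources, and 0 for every other comparison with list tests (acetate, glycerol, evolved lines on each of the 4 sources, each of the 4 alternating strains, the specialists against each other and the dependence of their difference on the source).

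Leaving out each library in turn gave 511 to 825 genes for acetate, 0 to 1 for glycerol, 13 to 34 for xylose and 0 to 176 for evolved lines over all sources. For evolved lines the ranges were 78 to 368 on glucose, 32 to 266 on glycerol, 1 to 101 on xylose, 0 to 140 on acetate and 53 to 473 for the dependence on the source. For the alternating strains they were 0 to 15 for Glc/Gly Generalist, 0 to 1 for Glc/Xyl Generalist, 1 to 9 for Glc/Ac Glc Specialist, 1 to 6 for Glc/Ac Ac Specialist, 0 to 3 between the specialists and 7 to 14 for the dependence of their difference. Lists ranged from 14 to 17 for acetate, 8 to 12 for glycerol, 8 to 17 for xylose, 7 to 13 for evolved lines over all sources, 10 to 12 on glucose, 10 to 17 on glycerol, 9 to 14 on xylose and 7 to 12 on acetate. They were 6 to 13 for Glc/Gly and 7 to 17 for Glc/Xyl Generalist. They were 4 to 12 for Glc/Ac Glc and 2 to 11 for Glc/Ac Ac Specialist, and 1 to 13 between the specialists. The dependence of their difference had 10, its 4 libraries never left out.

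Of 146 list calls with the preset correlation, the median turned its sign in 11 with FPKM as deposited, in 1 with quantile normalization and in 2 among genes of 600 nt or more (ribosomal proteins, to -0.16 for evolved lines on glucose and -0.23 for Glc/Ac Glc Specialist). With a term for the library set 9 of 88 turned, among them ribosomal proteins for xylose (-0.56 to 0.07), for evolved lines over all sources (0.45 to -0.17), for Glc/Ac Glc Specialist (0.38 to -0.27) and between the specialists (0.99 to -0.19), and flagella and chemotaxis for xylose (1.33 to -0.55) and for Glc/Ac Glc Specialist (-0.95 to 0.57). In the second library set alone 5 of 89 turned, and without Ac2 4 of 146. Leaving out 1 library ended 76 of 146 calls and moved the median by over 1.5 times for 71. They include 12 of 12 between the specialists and 9 of 9 for glycerol. The 10 medians for the dependence of their difference could not move.

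Of 131 named genes past the threshold 86 stayed past it in each of these fits and 45 did not. Within the second library set 13 of the 88 that were tested stayed past it, with a term for the set 37 of 85, and with only strains on 2 or more carbon sources 2 of 76. With FPKM as deposited 118 of 131 stayed past it, with quantile normalization 115 and without the trend or robust variance 130.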

Other observations

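The tests on the xylose genes, on cspC and on other splits of the samples, and the tests on the glycerol genes except the correlation with the wild type difference, were chosen only after the result was seen, and so was the control for that correlation.

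In a scan with no test, runs of neighbouring genes stood apart in single libraries. In Ac2 the sulfate assimilation genes from cysA to cysP (2539717 to 2543528) lay at 3.88 to 21.2 scaled FPKM against at least 129.5 in the other acetate libraries, with cysC to cysD and cysH to cysJ also lower. The same library had 12 flagellar genes from flgN to flgJ at 150.8 to 3510.2 against at most 64.0, and 6 maltose genes from malG to malM (4242626 to 4250474) at 408.4 to 3680.7 against at most 179.9. In Gly1 and in the wild type on xylose the copper and silver export genes from cusC to cusA (595600 to 601857) lay at 2.38 to 9.89 and at 1.61 to 5.74, against at least 37.4 and 91.7 in the other libraries of their sources. The library labelled Glc/Gly Generalist on glycerol had the enterobactin genes from entC to entH (624885 to 629713) at 71.8 to 124.8 against at most 7.79, and Ac3 had narY to narU at 42.0 to 91.9 against at most 7.39. In both libraries of a strain, cspC was lower and azuC higher in Glc/Ac Glc Specialist, and no gene met the rule in both libraries of the other 3 alternating strains.

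In the library labelled Glc1 on glucose the glycerol genes were on, in the one labelled Gly2 on glycerol they were off, and across genes, which are not independent replicates, the first correlated most with Gly1 (r = 0.963) and the second with Glc3 (r = 0.980). A change in the glycerol genes alone is argued against, since over 2775 other protein genes of 600 nt or more the library labelled Glc1 had r = 0.938 with Glc2 and Glc3 and r = 0.978 with Gly1, a difference of -0.0400. An exchange of the labels was tested first by a correlation with wild type glycerol minus wild type glucose, where clearly positive values had been set as its mark, and by that rule the values found, -0.182 for labelled Glc1 minus Glc2 and Glc3 and -0.223 for Gly1 minus labelled Gly2, exclude it. That rule was then set aside as void because Gly1 minus Glc2 and Glc3, libraries whose labels are not in doubt, also had a correlation of -0.193 with the wild type difference, which therefore does not follow the carbon source in these lines. The 2 differences within a label correlated with each other at 0.770, but the bounds of that test were set once its value was known. That test therefore carries little weight by itself, and an exchange remains a candidate explanation that is not settled. No biological explanation other than a change in the glycerol genes alone was tested.

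In the library labelled Glc/Gly Generalist on glycerol the xylose genes were on together with the glycerol genes. If RNA of a xylose-grown culture was mixed in, the xylose genes need a share of 1.11 of the xylose libraries. The glycerol genes need 0.835 of the wild type and Gly1 (labelled Gly2 left out), a sum of 1.94 over 15 genes. This cannot decide, as this strain had glpK, glpF and glpD high on glucose too. Xylose genes on in this strain on every source are argued against by its glucose library, whose 7 xylose genes lay a median of 0.37 (log2) above the other glucose libraries. Labels exchanged with the library labelled Glc/Xyl Generalist on xylose are argued against by that library, whose 8 glp genes lay at a median of -0.26 from the other xylose libraries. A culture that met both sugars, another wrong label and a change of the strain that acts on glycerol alone stay open and were not tested.

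Transcripts of cspC were listed at 0 in Glc/Ac Glc Specialist and at low levels in Glc/Ac Ac Specialist. Failed estimates of short genes are argued against, since of 124 values of 31 other abundant genes of 150 to 270 nt in these libraries 0% lay at a 50th or less of the median elsewhere. Reads given to another csp gene are argued against in Glc/Ac Ac Specialist, where yobF, which is no csp gene, reached 287.9 scaled FPKM, 0.235 times the lowest value of the other 18 libraries (1222.8). In Glc/Ac Glc Specialist the 8 csp paralogs together stood at 3.95 times the median of the wild type and single-substrate libraries on glucose and 1.13 times on acetate, so reads given to them cannot be told apart from a loss of the transcript there. Mutations at cspC in each strain may explain the pattern, as a hypothesis, and DNA sequences were not analysed here.

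Other splits of the samples into groups of the same sizes were counted for 4 comparisons, 100 splits each with the real one. For acetate against glucose 1 split, the real one, gave as many as 735 genes, the highest other gave 55, and chance can be excluded. With sources exchanged only within each library set, 1 of 100 splits, the real one, gave as many for acetate and the highest other gave 328, and chance can be excluded there too. For xylose 2 of 100 gave as many as 23, the real one included, with 34 as the highest other, a split that like the real one put all 4 glucose libraries of the first set on the same side. With sources exchanged only within each library set, 6 of 100 splits gave as many for xylose and the highest other, which kept 4 of the 5 xylose libraries together, gave 138, so once the set is held fixed chance cannot be excluded for this count, and within the second library set 6 genes passed. For glycerol and for evolved lines against wild type the real count was 0, which all 100 splits reach whatever the data, so the count of splits says nothing there, and the highest others gave 34 and 43 genes.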
